A study of Homo sapiens and Mus musculus with 27 samples.

How the data were processed

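RNA was measured in 27 libraries from 3 experiments with 3 groups of 3 replicates each. Per the labels, human LM2 and mouse 4T1 breast cancer cells carried a control, MKL1 or caMKL1 construct, and LM2 cells were negative, low or high in expression of the actin reporter LifeAct. In both lines the genotype labels of the caMKL1 samples run caMKL1, caMKL2 and caMKL3 over the replicates, while titles and treatment labels give caMKL1, and these samples were taken as caMKL1 replicates. Per the labels' protocols, RNA was extracted with TRIzol and sequenced as 150 bp paired-end reads on a HiSeq 2500, with adaptors and low-quality sequence removed. LM2 and 4T1 libraries were polyA selected, and LifeAct libraries were depleted of ribosomal RNA, per the same protocols. The labels do not give the construct sequences or say whether replicates came from separate cultures, and the column descriptions carry no batch.

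The deposited values are counts of read pairs per gene name. Per the file headers they were made with featureCounts v2.0.1 on STAR alignments, with exon features summed by gene name against Ensembl release 103 (GRCh38) or release 102 (GRCm38). The STAR version is not given in the sources used here. The headers show no strand option, so antisense overlaps can be counted at either gene, and no option for multi-mapped or multi-overlapping reads, which that tool leaves uncounted by default. The submitters' processing notes list featureCounts, DESeq2, hg38 and mm10. All 27 columns were matched to samples, and 0 were left unmapped. Summing by name merged 31 names on more than 1 chromosome in the human tables and 7 in the mouse table, for which no coordinates are given.

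Library totals ran from 22147429 to 32147377 counts in LM2, 21896459 to 29370432 in 4T1 and 15581289 to 23678322 in LifeAct. Of 59453 human names, 18893 passed edgeR's filter on low counts (minimum count 10, by group) in LM2 and 21869 in LifeAct, and of 55367 mouse names 16297 passed. Library sizes were scaled by TMM, computed within each experiment. The biological coefficient of variation was 0.118 in LM2, 0.0345 in 4T1 and 0.0439 in LifeAct. Replicate pairs differed by more than sampling noise, with a chi-square per gene of 1.39 to 53.0 over 27 pairs of libraries.

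Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with a mean per group fitted to the 9 libraries of an experiment, and p-values adjusted by Benjamini-Hochberg at 0.05. Log2 ratios come from that fit with a prior count of 0.125, and CPM values are TMM-scaled. Where a group had no count for a gene, the fold is a floor that sets the group to 3 counts, written "at least". Where it had 1 to 3 counts, the ratio has an exact 95% counting interval. For such genes the fitted log2 ratio depends on the prior count and is no bound. Comparisons were each treated group against its control or negative group and the treated groups against each other, 9 in all.

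The 30 fixed lists, written from general knowledge before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the 30 lists of a comparison. Some lists share members, so their calls are not independent. ACTA2, ACTG2 and CNN1 are among the genes in both the MRTF-SRF and smooth muscle lists. CCN1, CCN2 and ANKRD1 are in both the MRTF-SRF and YAP-TEAD lists. The camera test was repeated with a correlation estimated per list, and with fry. Counts of members use p adjusted over all tested genes, and a further pair of counts uses p adjusted over the list alone. Lists enter the report with their result in the comparison where they are named. Results for some genes and lists that this and the next rule would name are not reported here.

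Genes were named by a rule fixed before the data were examined. Always named were MRTFA, MRTFB, SRF, ACTA2, ACTB, ACTG1, TAGLN, CNN1, MYL9, TPM1, VCL, CCN1 and CCN2. Added were the 6 largest rises and 6 largest falls of each comparison with control (4 and 4 between treated groups) among genes with adjusted p under 0.05, at least 5 CPM over the libraries compared and no overlap between the groups' ranges. Up to 4 members of each described list with the smallest p were also open to naming. Unnamed clones could be counted without being named, which applied to 3 genes.

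Overlaps of calls were set beside the number for independent calls, and for groups that share controls beside 20 simulations of unchanged groups per experiment. Human and mouse genes were matched by symbol, 10361 in all, and the difference between the lines was tested as an interaction in a fit to 18 libraries. Fisher's exact test was used for LM2 caMKL1 against LifeAct high, experiments that also differ in RNA selection. It takes genes as independent units, so its p-values measure no spread between libraries and can be too small where genes vary together.

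Alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom, DESeq2 size factors, library totals, no filter, a filter of 50 counts in 3 libraries, only the 6 libraries compared, changes beyond 1.5-fold (glmTreat), a replicate block, and leaving out each library in turn. Added after seeing the data were a fit without replicate 1 of MKL1 and of caMKL1 in LM2, which had the larger chi-square per gene against their group, and leave-outs for the correlations. Nothing was removed from the main fits, and sequence reads were not used here.

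The edgeR test was tested on simulated data with 200 changed genes per comparison, 50 at each fold. At 1.5-fold it recovered 52%, 48% and 60% of genes in the LM2 comparisons (MKL1, caMKL1, and caMKL1 against MKL1), 86%, 86% and 78% in 4T1, and 76%, 78% and 74% in LifeAct (low, high, and high against low). At 2-fold the shares were 90%, 86% and 90%, then 98%, 98% and 94%, then 86%, 92% and 86%. At 4-fold they were 98% or 100%, and at 8-fold 100%. False calls made up 2.86%, 6.70% and 4.37% of calls in LM2, 5.88%, 8.13% and 2.11% in 4T1, and 8.12%, 6.57% and 2.72% in LifeAct. Only the 200 genes changed, with rises and falls in equal number, so library scaling was hardly put to the test. The real comparisons called 2265 to 15554 genes, and these shares need not hold there. The line difference recovered 40% at 1.5-fold and 90% at 2-fold, with 8.33% false. Camera found a planted list, made only of genes raised at least 2-fold, in each comparison and called 0 to 2 of 100 random lists. The simulated genes varied independently, so this says nothing on false calls for lists whose members vary together.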

Results

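In all 3 experiments the 3 libraries of each group lay together and apart from the other groups, and the largest axis of variation followed the treatment. Principal component 1 carried 93.2% of the variance of the 500 most variable genes in LM2 cells, 91.9% in 4T1 cells and 89.2% in LM2 cells grouped by LifeAct expression. Mitochondrially encoded genes made up 8.17 ± 0.67% of counts in LM2 control, 7.72 ± 1.92% in MKL1 and 11.6 ± 3.32% in caMKL1 libraries. In 4T1 cells the share was 2.92%, 3.23% and 2.64%, and in LifeAct negative, low and high libraries 4.11%, 3.74% and 4.05%. In LM2 the shares of replicates 1 to 3 were 6.18%, 9.87% and 7.11% with MKL1 and 7.76%, 13.4% and 13.6% with caMKL1. Replicate 1 differed from the others by a chi-square per gene of 52.68 and 37.04 with MKL1, where the others differed by 21.61, and of 48.58 and 52.96 with caMKL1, where the others differed by 3.13. The p-values below measure spread between these samples only, since the labels do not say whether replicates came from separate cultures.

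**Figure D1:**
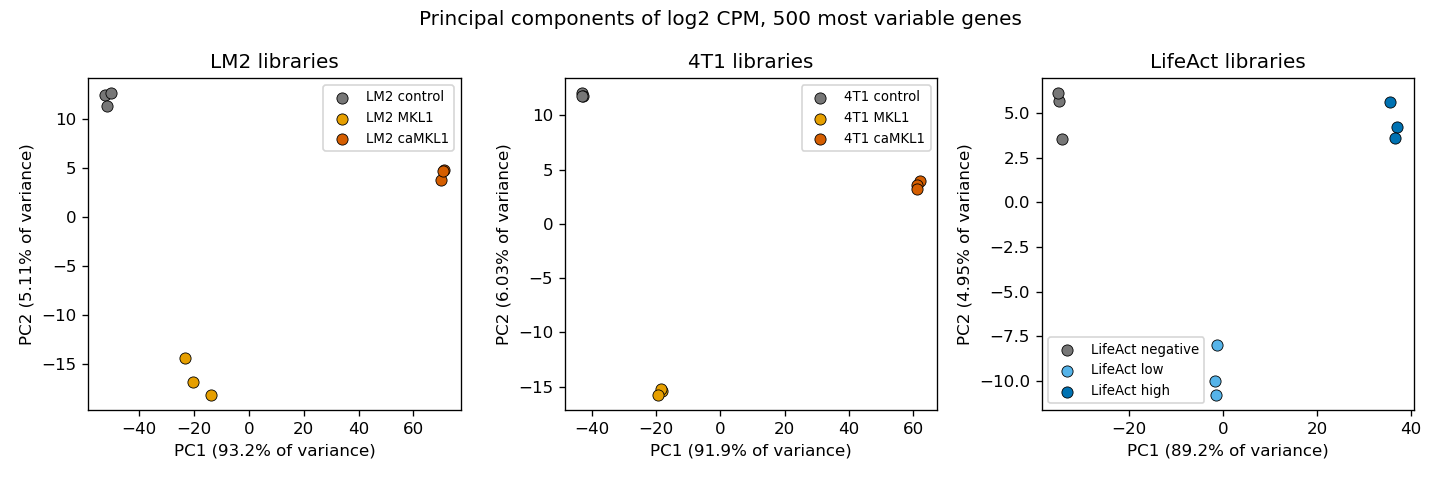
Principal components 1 (horizontal) and 2 (vertical), with the percentage of variance on each axis, of log2 CPM of the 500 most variable genes in LM2, 4T1 and LifeAct libraries; each point is a library coloured by group. The 3 libraries of every group lie nearer each other than to the other groups.

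MRTFA, the gene also called MKL1, rose 14.97-fold in LM2 cells of the MKL1 group, from 10.8 ± 0.641 to 162 ± 20.3 CPM (mean ± SD, n = 3, adjusted p = 2.5e-10, chr22:40410281-40636719, GRCh38). The labels do not give the introduced sequence, so the share of it counted at MRTFA is unknown. Its partner SRF rose 1.84-fold (31.5 to 58.1 CPM, adjusted p = 5.5e-05). Smooth-muscle alpha-actin ACTA2 went from 0.681 ± 0.176 to 104 ± 49.2 CPM (151-fold, adjusted p = 1.6e-09, chr10:88935074-88991339), and the actin-binding gene TAGLN from 3.52 ± 0.468 to 282 ± 119.8 CPM (80.0-fold, adjusted p = 8.0e-10, chr11:117199370-117207464). ACTG2, with 1 count in all control libraries, rose 15894-fold (95% counting interval 2852 to 627820), ACTC1 5831-fold (95% counting interval 1046 to 230336), and the channel subunit KCNMB1 at least 97.2-fold. Such intervals and floors cover counting error only, and the muscle actins are near-identical paralogs, so reads can be assigned to the wrong member. Keratin KRT17 rose 498-fold and the myosin light chain MYL9 11.1-fold. Cytoplasmic ACTB rose 2.75-fold and ACTG1 2.25-fold. The paralog MRTFB decreased by 0.39 on the log2 scale (adjusted p = 0.0197), a call lost when any one control library is left out (adjusted p = 0.0677 to 0.0817). The calponin gene CNN1 did not pass (adjusted p = 0.126).

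Among matrix and adhesion genes, fibronectin FN1 rose 6.14-fold (264.7 to 1624 CPM), collagen COL6A3 6.41-fold, integrin ITGA5 3.37-fold and tenascin TNC 2.96-fold. The YAP-TEAD target CCN2 rose 4.18-fold, coagulation factor F3 2.84-fold, MYC 2.13-fold and KRT7 2.95-fold. The interferon-stimulated genes ISG15 and IFIT2 rose 7.15-fold and 2.94-fold, and the cytokine CSF2 5.13-fold. Large falls among genes of at least 5 CPM were those of GNG7 (log2 ratio −1.59), the adhesion molecule BCAM (−1.56), EPHA7 (−1.55), PPL (−1.47) and ZNF641 (−1.39). The cytokine IL11 also fell (−1.05).

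Among the 34 tested MRTF-SRF cytoskeletal targets, 31 of 34 rose, 1 fell and 2 did not pass (31 and 2 adjusted over the list alone, camera adjusted p = 1.6e-31, adjusted p = 0.0504 with an estimated correlation). Of the smooth muscle genes, 8 of 12 rose, 0 fell and 4 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.0663 with an estimated correlation). For immediate early genes, 14 of 21 rose, 1 fell and 6 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 2.7e-08, adjusted p = 0.0663 with an estimated correlation). Focal adhesion and integrin genes kept their call, as 10 of 27 rose, 2 fell and 15 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 1.8e-06, adjusted p = 0.0383 with an estimated correlation). Of collagens and matrix genes, 12 of 21 rose, 1 fell and 8 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 1.1e-12, adjusted p = 0.0511 with an estimated correlation). The lung metastasis genes gave this split: 9 of 15 rose, 0 fell and 6 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 2.5e-07, adjusted p = 0.0504 with an estimated correlation). Among TGF-beta response genes, 10 of 13 rose, 1 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 4.1e-08, adjusted p = 0.0663 with an estimated correlation). Of interferon-stimulated genes, 8 of 22 rose, 0 fell and 14 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.0925 with an estimated correlation). Of NF-kB and cytokine genes, 8 of 16 rose, 1 fell and 7 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 1.4e-04, adjusted p = 0.0663 with an estimated correlation). In the glycolysis and hypoxia list, 11 of 21 rose, 0 fell and 10 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 3.8e-09, adjusted p = 0.134 with an estimated correlation). Mitotic genes stayed largely below the threshold: 2 of 21 rose, 0 fell and 19 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.134). Ribosomal proteins made up 3.63% of counts in MKL1 replicate 1, 2.54% and 2.60% in replicates 2 and 3 and 2.52% to 2.61% in control, and 30 of 30 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.469 with an estimated correlation). The fibroblast markers had mixed signs, as 1 of 4 rose, 0 fell and 3 did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.579, median −0.29, mean 0.49, test direction down).

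By edgeR quasi-likelihood tests 1369 genes were higher and 896 lower of 18893 tested, and 506 of the rises were at least 2-fold. With library totals in place of TMM the split was 918 higher and 1241 lower. Without replicate 1 of MKL1 and of caMKL1, 2890 genes were called, and without control replicate 3, 1118. Leaving out either other control library also lowered the count by more than 1.5 times.

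In LM2 cells with caMKL1, MRTFA went from 10.8 ± 0.641 to 218.3 ± 41.5 CPM (20.2-fold over control, adjusted p = 9.8e-13) and ACTA2, ACTB and MYL9 stood above the MKL1 group. ACTA2 went from 0.681 ± 0.176 to 2120.3 ± 90.1 CPM (3080.2-fold, adjusted p = 4.8e-13), ACTB from 2310.3 ± 48.5 to 22353 ± 952 CPM (9.68-fold, chr7:5526409-5563902), and SRF rose 4.50-fold. ACTG2 rose 303367-fold (95% counting interval 54448 to 11982400) and ACTC1 190971-fold (95% counting interval 34275 to 7542990). Genes with no control count included the smooth-muscle long noncoding RNA CARMN (at least 2172-fold), KCNMB1 (at least 1983-fold), the neuronal RNA-binding gene ELAVL4 (at least 1912-fold) and the myosin chaperone UNC45B (at least 1805-fold). TAGLN rose 336-fold, MYL9 41.1-fold, CNN1 5.35-fold, tropomyosin TPM1 4.21-fold, vinculin VCL 5.82-fold, CCN1 6.31-fold and CCN2 33.5-fold. MRTFB decreased by 1.79 on the log2 scale (70.6 to 20.4 CPM, adjusted p = 6.0e-10).

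Among matrix and adhesion genes, FN1 rose 27.4-fold with caMKL1 (264.7 to 7261 CPM), ITGA5 25.2-fold, ITGA1 19.1-fold and TNC 16.6-fold. The immediate early genes EGR3 and FOS rose 257-fold and 59.6-fold, the cyclin-dependent kinase inhibitor CDKN1A 31.3-fold, the peptide transporter TAP1 28.4-fold, KRT19 23.6-fold and the prostaglandin synthase PTGS2 19.1-fold. Cell-cycle genes fell: topoisomerase TOP2A went from 1059 ± 51.8 to 159 ± 8.005 CPM (log2 ratio −2.73, adjusted p = 2.3e-12, chr17:40388525-40417896), ribonucleotide reductase RRM2 from 223 to 35.7 CPM (−2.64) and the checkpoint kinase BUB1 from 198 to 32.5 CPM (−2.60). The polyadenylated signal of the histone genes H1-4 and H2AC11 rose 11.1-fold and 8.05-fold. The largest falls were the transcription factor ZNF521 (−3.74), the TGF-beta co-receptor ENG (−3.53), CADM2 (−3.47), BCAM (−3.45), MAGEA3 (−3.43) and heparanase HPSE (−3.35). The receptor kinase AXL (−2.15) and the cytokines IL11 (−2.32) and CSF1 (−2.14) also fell.

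Of the 34 MRTF-SRF targets, 30 of 34 rose, 3 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.4e-12, adjusted p = 0.156 with an estimated correlation). Among the 12 smooth muscle genes, 10 of 12 rose, 0 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.156 with an estimated correlation). Striated muscle genes divided as follows: 5 of 6 rose, 1 fell and 0 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.0898). Among immediate early genes, 17 of 21 rose, 3 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 7.0e-06, adjusted p = 0.156 with an estimated correlation). Focal adhesion and integrin genes were mostly higher, as 17 of 27 rose, 5 fell and 5 did not pass (17 and 6 adjusted over the list alone, camera adjusted p = 0.00120, adjusted p = 0.105 with an estimated correlation). In the matrix list 18 of 21 rose, 2 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 5.4e-07, adjusted p = 0.156 with an estimated correlation). YAP-TEAD targets depended on scaling, since 11 of 22 rose, 5 fell and 6 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.0561, median 0.36 but −0.04 with library totals). The actin assembly and turnover list likewise had 15 of 33 members higher, 8 lower and 10 not passing (unchanged when adjusted over the list alone, camera adjusted p = 0.290, median 0.26 but −0.16 with library totals). Epithelial genes gave no set call, with 10 of 16 members higher, 4 lower and 2 not passing (unchanged when adjusted over the list alone, camera adjusted p = 0.0823). Among mesenchymal genes, 5 of 9 rose, 3 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.281). Proteases and inhibitors were mixed, as 6 of 15 rose, 5 fell and 4 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.836, median −0.11, mean 0.29, test direction up).

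Proliferation genes were lower without exception. Of the mitotic genes, all 21 fell (unchanged when adjusted over the list alone, camera adjusted p = 1.5e-13, adjusted p = 0.0653 with an estimated correlation). Of the replication genes, all 21 fell (unchanged when adjusted over the list alone, camera adjusted p = 1.4e-10, adjusted p = 0.270 with an estimated correlation). Of the mitochondrially encoded messenger RNAs, beside mitochondrial shares of 13.4% and 13.6% in replicates 2 and 3 but 7.76% in replicate 1, all 13 rose (unchanged when adjusted over the list alone, camera adjusted p = 0.00936, adjusted p = 0.589 with an estimated correlation). For ribosomal proteins, 0 of 30 rose, 19 fell and 11 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 5.3e-04, adjusted p = 0.589 with an estimated correlation). Of the replication-dependent histones, all 6 rose (unchanged when adjusted over the list alone, camera adjusted p = 0.00120, adjusted p = 0.156 with an estimated correlation). Cholesterol synthesis genes were mostly lower, with 5 of 21 members higher, 13 lower and 3 not passing (6 and 14 adjusted over the list alone, camera adjusted p = 0.0471, adjusted p = 0.574 with an estimated correlation). The endothelial markers, all low in level, went down: all 4 fell (unchanged when adjusted over the list alone, camera adjusted p = 0.0471, adjusted p = 0.270 with an estimated correlation). Of p53 targets, 7 of 12 rose, 3 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.121, median 0.29 but −0.12 with library totals). Unfolded protein and stress response genes again turned with scaling, as 8 of 15 rose, 3 fell and 4 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.0898, median 0.38 but −0.03 with library totals). The leukocyte list, with 2 tested members, had 1 of 2 members higher, 0 lower and 1 not passing (unchanged when adjusted over the list alone, camera adjusted p = 0.462).

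Of 18893 tested genes 6030 were higher and 6241 lower (edgeR), with 3702 and 2870 changed at least 2-fold. Under library totals the split was 4137 and 9271, where the median of all genes shifts by −0.46, and the falls given here are relative to TMM scaling. Without replicate 1 of MKL1 and of caMKL1 the call count was 13053.

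**Figure D2:**
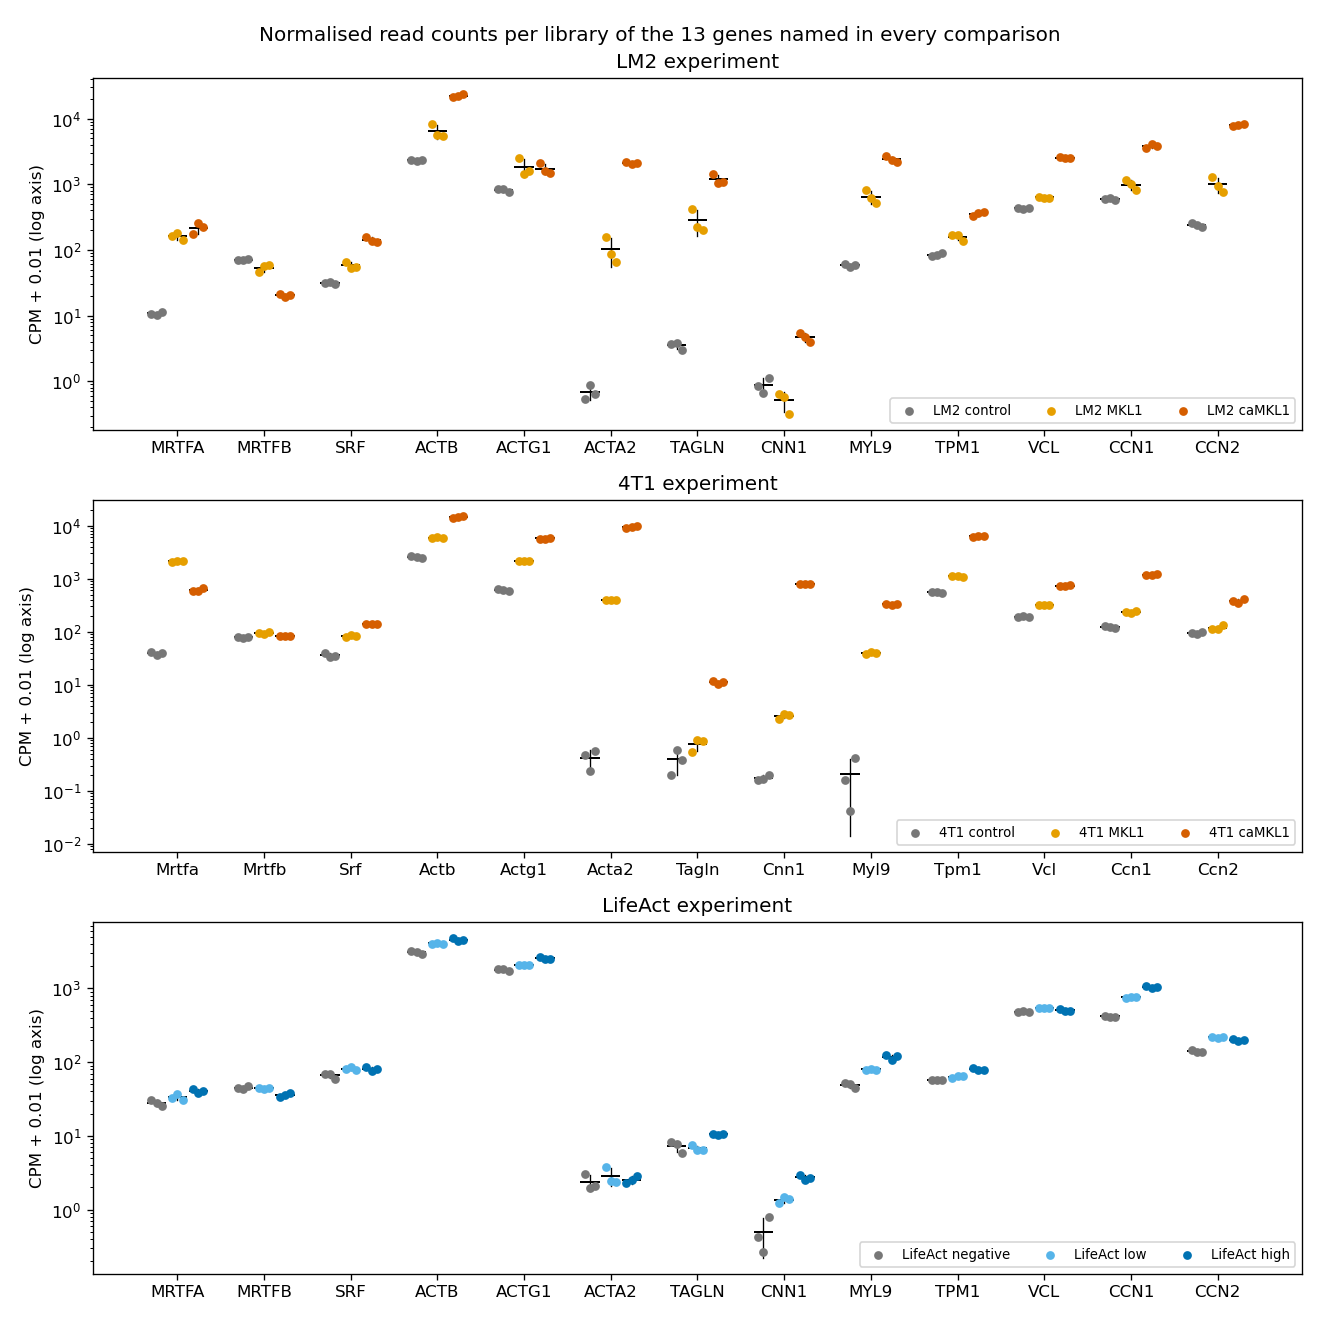
Expression of MRTFA, MRTFB, SRF and 10 of their cytoskeletal targets in CPM plus 0.01 on a log axis, for the 3 groups of LM2, 4T1 and LifeAct libraries; points are libraries and lines give mean ± SD. ACTA2 and MYL9 rise in steps from control to MKL1 to caMKL1 in LM2 and 4T1 cells. With LifeAct expression MYL9 and CNN1 rise in steps from negative to low to high, and ACTA2 does not.

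The LM2 constructs were also compared directly. As the introduced sequences are not given, MRTFA counts need not follow construct level here. MRTFA differed by 0.43 on the log2 scale (162 to 218.3 CPM, adjusted p = 0.00695), a call that was lost with library totals (adjusted p = 0.451). ACTA2 was 20.4-fold higher with caMKL1 (adjusted p = 4.0e-10), VCL 4.00-fold, ACTB 3.52-fold and CCN2 8.001-fold, while ACTG1 did not pass (adjusted p = 0.631). ELAVL4 rose at least 2176-fold, UNC45B 189-fold, the myosin kinase MYLK 16.7-fold and the early gene EGR1 17.5-fold. The transporter SLCO4A1 (−3.82), ZNF521 (−3.49), ENG (−3.39) and LINC00973 (−3.38) had the largest negative log2 ratios. Some genes higher in the MKL1 group than in control were lower here, among them the plasminogen activator PLAU (−2.45) and the chemokine CXCL8 (−2.87). TOP2A (−2.83) and RRM2 (−3.17) fell as they did against control.

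Of MRTF-SRF targets, 26 of 34 rose, 2 fell and 6 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.9e-08, adjusted p = 0.275 with an estimated correlation). Of the smooth muscle genes, 10 of 12 rose, 0 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 2.9e-06, adjusted p = 0.170 with an estimated correlation). Among mitotic genes, all 21 fell (unchanged when adjusted over the list alone, camera adjusted p = 2.2e-14, adjusted p = 0.0600 with an estimated correlation). In the replication list all 21 fell (unchanged when adjusted over the list alone, camera adjusted p = 6.6e-12, adjusted p = 0.275 with an estimated correlation). The NF-kB and cytokine list had 4 of 16 members higher, 10 lower and 2 not passing (unchanged when adjusted over the list alone, camera adjusted p = 0.0954). For lung metastasis genes, 7 of 15 rose, 7 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.591, median 0.13 but −0.21 with library totals). The edgeR test called 6150 genes higher and 6029 lower, against 4425 and 8635 with library totals, where the median gene moves by −0.38.

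In 4T1 mouse cells of the MKL1 group Mrtfa rose from 39.2 ± 2.28 to 2145 ± 56.2 CPM (54.8-fold, adjusted p = 5.7e-29, chr15:81012281-81190757, GRCm38). As the introduced sequence and its species are not given, these counts need not measure construct level in 4T1 cells. Acta2 went from 0.416 ± 0.174 to 400.3 ± 1.61 CPM (975-fold, adjusted p = 1.7e-30, chr19:34241090-34255590), Actg2 rose 1759.7-fold (95% counting interval 602 to 8536), Acta1 684-fold and Actc1 at least 35.3-fold. Myl9 rose 204-fold, Tpm2 36.5-fold, Cnn1 15.1-fold, Actg1 3.52-fold, Actb 2.29-fold and Srf 2.29-fold. Tagln, below 1 CPM in each group, passed narrowly (1.92-fold, adjusted p = 0.0357). The matrix genes Col12a1 and Thbs1 rose 4.07-fold and 2.40-fold. The interferon-stimulated genes Ifit3, Ifi44 and Irf7 rose 5.32-fold, 3.64-fold and 2.93-fold. The macrophage-associated lysosomal gene Cd68 rose 3.36-fold, while the other tested leukocyte marker did not pass. The falls were smaller, led by the borate transporter Slc4a11 (log2 ratio −1.58), Ramp1 (−1.43), Gstm5 (−1.30), Irf8 (−1.26), Col6a2 (−1.16) and Htr5b (−1.15). The gelatinase Mmp9 decreased by 1.02 on the log2 scale.

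MRTF-SRF targets kept their call, as 33 of 34 rose, 0 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.4e-39, adjusted p = 0.00580 with an estimated correlation). So did smooth muscle genes, where 10 of 14 rose, 0 fell and 4 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 8.6e-09, adjusted p = 0.0151 with an estimated correlation). Of the actin assembly list, 22 of 32 rose, 2 fell and 8 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 7.7e-11, adjusted p = 0.0105 with an estimated correlation). In the interferon list all 20 rose (unchanged when adjusted over the list alone, camera adjusted p = 7.7e-20, adjusted p = 0.0726 with an estimated correlation). In antigen presentation all 9 rose (unchanged when adjusted over the list alone, camera adjusted p = 4.0e-14, adjusted p = 0.0219 with an estimated correlation). Mesenchymal genes were raised, with 7 of 9 members higher, 0 lower and 2 not passing (unchanged when adjusted over the list alone, camera adjusted p = 3.5e-04, adjusted p = 0.0280 with an estimated correlation). The protease list had 12 of 18 members higher, 1 lower and 5 not passing (unchanged when adjusted over the list alone, camera adjusted p = 1.8e-06, adjusted p = 0.0127 with an estimated correlation). Replication genes were slightly lower (median −0.28), since 0 of 21 rose, 19 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.4e-11, adjusted p = 0.0726 with an estimated correlation). Ribosomal proteins were lower too, where all 30 fell (unchanged when adjusted over the list alone, camera adjusted p = 3.6e-17, adjusted p = 0.0687 with an estimated correlation). Of unfolded protein response genes, 2 of 15 rose, 8 fell and 5 did not pass (2 and 9 adjusted over the list alone, camera adjusted p = 0.00671, adjusted p = 0.238 with an estimated correlation). The endothelial and leukocyte lists had 2 tested members each and the mouse histone list 1, H2bc4, which rose 1.85-fold and allows no set test.

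The edgeR counts were 3144 higher and 2449 lower of 16297 tested, with 472 and 127 beyond 2-fold. Library totals gave 2324 and 3868.

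With caMKL1 in 4T1 cells Mrtfa was at 624 ± 47.4 CPM (15.9-fold over control). Acta2 rose to 9423 ± 276 CPM (22952-fold, adjusted p = 3.1e-35), Actg2 98006-fold (95% counting interval 33536 to 475243), Acta1 10344-fold, Actc1 at least 18317-fold, and the muscle genes Myo18b and Pdlim3 at least 2203-fold and at least 1650.1-fold. Cnn1 went from 0.167 ± 0.0186 to 795 ± 4.36 CPM (4626-fold, chr9:22099216-22109630), Myl9 rose 1686-fold, smooth-muscle myosin Myh11 768-fold, Tpm1 11.4-fold, Actg1 9.36-fold, Itga5 19.1-fold and Ccn1 9.61-fold. The interferon-stimulated gene Ifit2 rose 8.04-fold, Cd68 9.72-fold and the cathepsin gene Ctsb 4.22-fold. The other tested leukocyte marker fell. The metalloprotease Adamts9 had the largest fall (15.2 to 0.226 CPM, log2 ratio −6.02), followed by Angptl4 (−5.40), the leukocyte integrin Itgb2 (−4.78), Slc4a4 (−4.77), Irf8 (−4.28) and Sox5 (−3.82). Mmp9 (−3.72), Egr1 (−3.70) and Vcam1 (−1.73) fell too, and Rrm2 and Uhrf1 changed by −1.47 and −1.49.

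Of the MRTF-SRF targets, 33 of 34 rose, 0 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 3.5e-20, adjusted p = 0.0338 with an estimated correlation). For smooth muscle genes, all 14 rose (unchanged when adjusted over the list alone, camera adjusted p = 1.5e-08, adjusted p = 0.0338 with an estimated correlation). Among striated muscle genes, 8 of 10 rose, 2 fell and 0 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.0825). Matrix genes were mostly higher, with 15 of 19 members higher, 3 lower and 1 not passing (unchanged when adjusted over the list alone, camera adjusted p = 8.4e-05, adjusted p = 0.123 with an estimated correlation). In antigen presentation, all 9 rose (unchanged when adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.123 with an estimated correlation). Oxidative phosphorylation genes leaned upward, as 16 of 21 rose, 0 fell and 5 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.140 with an estimated correlation). Of stress response genes, 13 of 15 rose, 0 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 5.9e-05, adjusted p = 0.140 with an estimated correlation). Replication genes were lower, with 1 of 21 members higher, 18 lower and 2 not passing (2 and 18 adjusted over the list alone, camera adjusted p = 2.0e-06, adjusted p = 0.210 with an estimated correlation). Most mitotic genes fell, where 3 of 21 rose, 16 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 4.2e-04, adjusted p = 0.325 with an estimated correlation). Of interferon-stimulated genes, 12 of 20 rose, 5 fell and 3 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.102). Ribosomal protein genes went down: 1 of 30 rose, 27 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.6e-08, adjusted p = 0.203 with an estimated correlation). The TGF-beta list gave no direction, as 6 of 13 rose, 6 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.819, median 0.01 but −0.17 with library totals).

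In all, 5900 genes were higher and 5841 lower (edgeR), 2178 and 1421 by at least 2-fold, against 4528 and 7580 with library totals, where the median gene moves by −0.21.

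Between the 4T1 constructs the Mrtfa count was lower with caMKL1 (log2 ratio −1.78, adjusted p = 2.0e-21), which need not follow construct level. Acta2 was 23.5-fold higher, Cnn1 306-fold and Srf 1.68-fold. The matrix proteoglycan Prelp rose 845-fold, Actc1 518-fold, endothelin Edn2 370.2-fold and the sodium-calcium exchanger Slc8a2 622-fold (95% counting interval 172 to 5145). Adamts9 (−5.70), Slc4a4 (−4.88), Itgb2 (−4.08), Sox5 (−3.98) and the stromelysin Mmp3 (−3.50) fell. The interferon-stimulated genes Ifi44 (−2.24) and Oas2 (−1.82) were lower with caMKL1 although Ifit2 was 4.60-fold higher. The stress genes Ppp1r15a and Chac1 rose 6.80-fold and 3.45-fold.

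Smooth muscle genes kept their call, as all 14 rose (unchanged when adjusted over the list alone, camera adjusted p = 2.5e-11, adjusted p = 0.0274 with an estimated correlation). Interferon-stimulated genes turned down, as 1 of 20 rose, 16 fell and 3 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 2.0e-04, adjusted p = 0.504 with an estimated correlation). Among stress response genes, all 15 rose (unchanged when adjusted over the list alone, camera adjusted p = 4.3e-07, adjusted p = 0.205 with an estimated correlation). Oxidative phosphorylation genes rose, as 19 of 21 rose, 1 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 9.1e-05, adjusted p = 0.205 with an estimated correlation). The edgeR test called 5505 genes higher and 5353 lower, or 4534 and 6690 with library totals, where the median gene moves by −0.13.

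In LM2 cells of the LifeAct low group the largest rises over the negative group were the mitochondrial ribosomal RNAs, MT-RNR1 from 2.71 ± 0.978 to 69.9 ± 38.4 CPM (25.6-fold, adjusted p = 7.6e-12) and MT-RNR2 from 3.32 ± 0.553 to 75.3 ± 39.3 CPM (22.5-fold). These libraries were depleted of ribosomal RNA, and copies of the mitochondrial genome in nuclear chromosomes add uncertainty to the assignment. The histone genes H4C15 and H4C14, near-identical copies whose reads are hard to separate, rose 8.89-fold and 7.78-fold, the interferon-stimulated gene OASL 5.63-fold and the cell-cycle factor E2F2 5.31-fold. RRM2 went from 32.03 ± 1.39 to 118 ± 1.86 CPM (3.67-fold, adjusted p = 1.6e-21). The replication licensing factor CDC6 rose 3.49-fold, MCM4 3.22-fold, MKI67 2.03-fold, IFIT2 3.58-fold, IL6 3.64-fold and CXCL8 2.80-fold. Integrin ITGA10 fell from 252 ± 5.37 to 26.5 ± 0.845 CPM (log2 ratio −3.25, adjusted p = 2.2e-26, chr1:145891208-145910111). Other falls were SLITRK6 (−2.86), RAB17 (−2.17), the transcription factor SOX4 (−2.07) and the hypoxia-induced gene NDRG1 (−1.63). FN1 (−1.13), ITGA1 (−1.76) and CSF1 (−1.20) were lower. Among MRTF-SRF genes ACTB rose 1.32-fold, MYL9 1.62-fold, CCN1 1.81-fold and MRTFA 1.18-fold, whereas ACTA2 (adjusted p = 0.351), TAGLN (adjusted p = 0.481) and MRTFB (adjusted p = 0.700) did not pass.

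Proliferation genes rose in the low group. Among mitotic genes, 20 of 21 rose, 0 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.6e-19, adjusted p = 0.00152 with an estimated correlation). Among replication genes, all 21 rose (unchanged when adjusted over the list alone, camera adjusted p = 5.6e-21, adjusted p = 0.0204 with an estimated correlation). Of histone genes, all 8 rose (unchanged when adjusted over the list alone, camera adjusted p = 4.5e-10, adjusted p = 0.0325 with an estimated correlation). Interferon-stimulated genes were higher, as 17 of 24 rose, 2 fell and 5 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.0204 with an estimated correlation). NF-kB and cytokine genes were higher, since 15 of 20 rose, 3 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.287 with an estimated correlation). Cholesterol synthesis genes were lower, with 2 of 21 members higher, 15 lower and 4 not passing (unchanged when adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.0275 with an estimated correlation). In the glycolysis and hypoxia list 2 of 21 rose, 18 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 7.4e-11, adjusted p = 0.0521 with an estimated correlation). Focal adhesion and integrin genes went down, as 5 of 25 rose, 14 fell and 6 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 6.9e-04, adjusted p = 0.0325 with an estimated correlation). For MRTF-SRF targets, 19 of 31 rose, 7 fell and 5 did not pass (19 and 8 adjusted over the list alone, camera adjusted p = 0.00695, adjusted p = 0.581 with an estimated correlation). Of the mitochondrial messenger RNAs, 1 of 13 rose, 8 fell and 4 did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.0711). The immediate early list had 7 of 21 members higher, 11 lower and 3 not passing (unchanged when adjusted over the list alone, camera adjusted p = 0.247, median −0.13, mean 0.04, test direction down).

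The edgeR test gave 5677 genes higher and 5169 lower of 21869 tested, 1193 and 1014 by at least 2-fold.

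In LifeAct high cells, compared with the negative group, CDC6 rose from 21.5 ± 1.69 to 139 ± 0.662 CPM (6.47-fold, adjusted p = 2.8e-25, chr17:40287879-40304657), OASL 16.01-fold, IFIT2 13.4-fold, the chemokine CXCL8 14.7-fold, IL6 9.05-fold and the stress gene ATF3 13.7-fold. KRT17, with 1 count in the negative libraries, rose 881-fold (95% counting interval 158 to 34815), and the plasminogen activator inhibitor SERPINB2 196-fold, MYPN 44.5-fold, SPX 40.6-fold, the long noncoding RNA UCA1 32.2-fold and the stromelysin MMP3 29.5-fold. The oxidase NOX5 fell from 84.6 ± 7.96 to 1.31 ± 0.212 CPM (log2 ratio −5.98, adjusted p = 1.9e-26, chr15:68930525-69062762), ITGA10 had −5.50, LINC01844 −5.12, the Wnt-induced gene CCN4 −4.56, RAB17 −4.43, PECAM1 −3.62, NDRG1 −3.29, CSF1 −1.98 and FN1 −1.84. ACTB rose 1.48-fold, MYL9 2.42-fold, the target ANKRD1 6.10-fold, CCN1 2.50-fold and MRTFA 1.45-fold, while ACTA2 (adjusted p = 0.702) and VCL (adjusted p = 0.108) did not pass.

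Of mitotic genes, 20 of 21 rose, 0 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 3.1e-11, adjusted p = 0.00751 with an estimated correlation). Of replication genes, all 21 rose (unchanged when adjusted over the list alone, camera adjusted p = 4.4e-13, adjusted p = 0.0343 with an estimated correlation). Interferon-stimulated genes were higher, with 19 of 24 members higher, 3 lower and 2 not passing (unchanged when adjusted over the list alone, camera adjusted p = 2.8e-06, adjusted p = 0.0151 with an estimated correlation). NF-kB and cytokine genes gave 17 of 20 members higher, 2 lower and 1 not passing (unchanged when adjusted over the list alone, camera adjusted p = 4.1e-07, adjusted p = 0.166 with an estimated correlation). Of cholesterol genes, 2 of 21 rose, 19 fell and 0 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 2.8e-06, adjusted p = 0.0151 with an estimated correlation). Glycolysis and hypoxia genes were lower, as 2 of 21 rose, 18 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 2.7e-08, adjusted p = 0.128 with an estimated correlation). Among MRTF-SRF targets, 20 of 31 rose, 5 fell and 6 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.00222, adjusted p = 0.519 with an estimated correlation). YAP-TEAD targets were mostly raised, as 16 of 22 rose, 4 fell and 2 did not pass (17 and 4 adjusted over the list alone, camera adjusted p = 3.0e-04, adjusted p = 0.248 with an estimated correlation). In the focal adhesion list 7 of 25 rose, 16 fell and 2 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.0414, adjusted p = 0.166 with an estimated correlation). In the matrix list 5 of 19 rose, 13 fell and 1 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.0452, adjusted p = 0.645 with an estimated correlation). Antigen presentation genes went up: 8 of 10 rose, 2 fell and 0 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.482 with an estimated correlation). For stress response genes, 11 of 15 rose, 2 fell and 2 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 4.1e-04, adjusted p = 0.216 with an estimated correlation).

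Here 7863 genes were higher and 7691 lower (edgeR), with 2488 and 3578 beyond 2-fold. Genes down at that size included the integrins ITGA1 (−2.40) and ITGB4 (−2.39) and the matrix gene LTBP1 (−2.01).

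**Figure D3:**
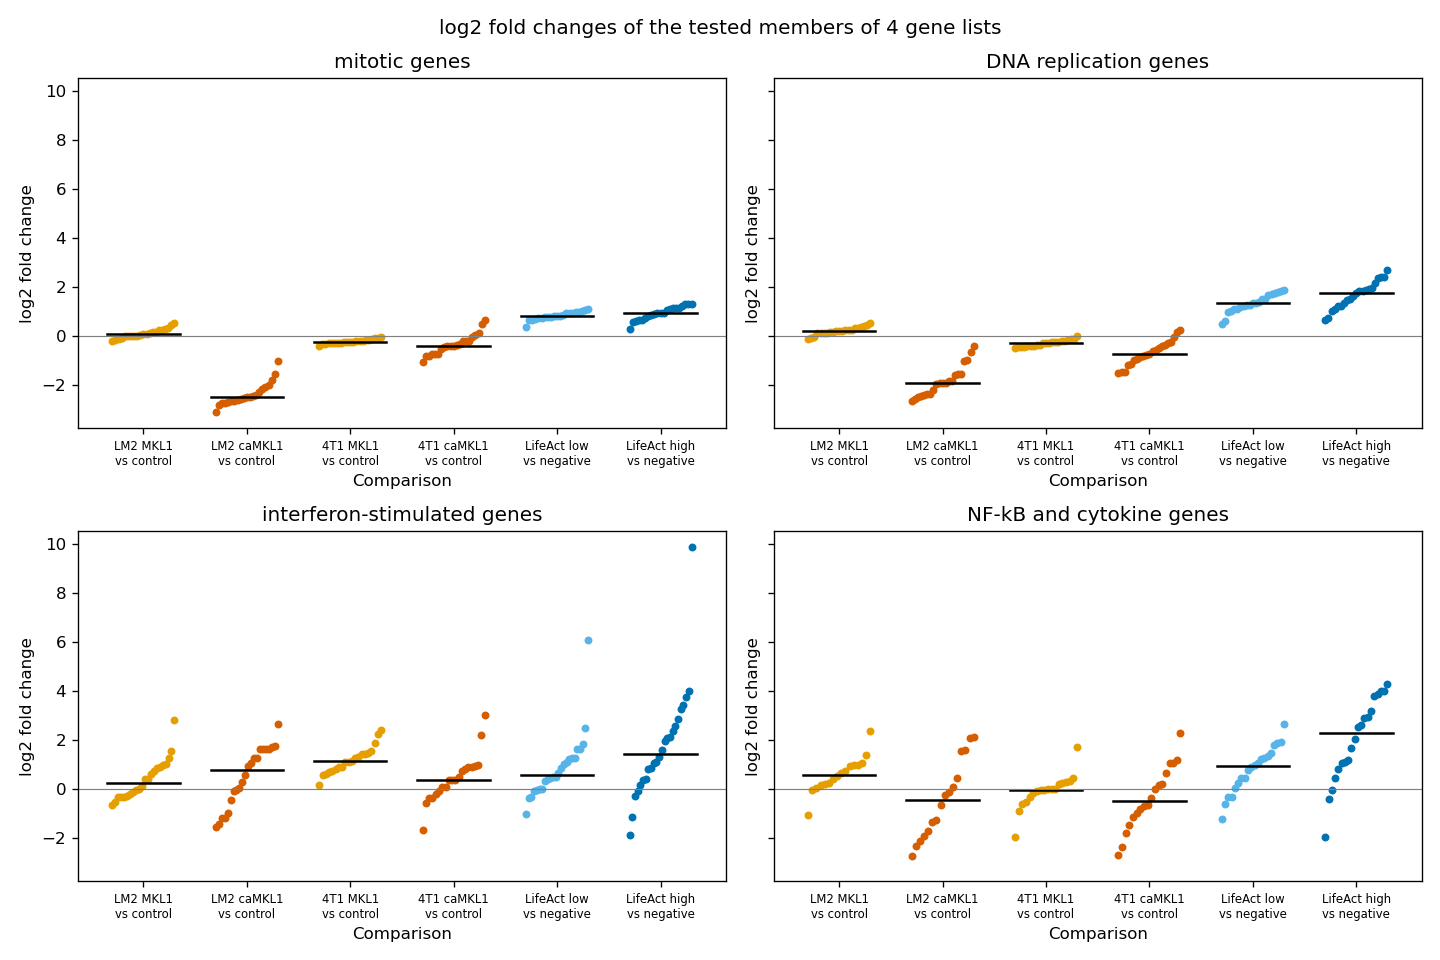
Log2 fold changes against control or LifeAct negative of the tested members of the mitotic, DNA replication, interferon-stimulated and NF-kB lists (panels) in 6 comparisons along the horizontal axis; points are genes and the line is the median. Mitotic and replication genes lie below 0 with caMKL1 in LM2 and above 0 in LifeAct low and high cells.

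Between LifeAct high and low, UCA1 rose 12.5-fold (4.47 to 55.8 CPM, adjusted p = 3.9e-22), SERPINB2 12.1-fold, ALOXE3 8.84-fold, KRT17 8.72-fold, CXCL8 5.25-fold, IL1A 5.75-fold and the NF-kB inhibitor TNFAIP3 5.56-fold. NOX5 fell again (−4.27), as did CCN4 (−2.76) and NDRG1 (−1.66). The mitochondrial MT-RNR1 fell from 69.9 to 4.16 CPM (log2 ratio −4.08) and MT-RNR2 from 75.3 to 5.98 CPM (−3.67). SRF did not pass (adjusted p = 0.955). Of interferon-stimulated genes, 18 of 24 rose, 3 fell and 3 did not pass (unchanged when adjusted over the list alone, camera adjusted p = 2.1e-08, adjusted p = 0.0158 with an estimated correlation). NF-kB and cytokine genes went up, as 16 of 20 rose, 1 fell and 3 did not pass (16 and 2 adjusted over the list alone, camera adjusted p = 9.6e-10, adjusted p = 0.163 with an estimated correlation). Cholesterol genes were lower still, with 1 of 21 members higher, 14 lower and 6 not passing (unchanged when adjusted over the list alone, camera adjusted p = 5.4e-06, adjusted p = 0.0260 with an estimated correlation). The histone list turned down, as 0 of 8 rose, 6 fell and 2 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 5.4e-06, adjusted p = 0.163 with an estimated correlation). The edgeR counts were 5828 higher and 5176 lower, or 4655 and 6437 with library totals, where the median gene moves by −0.11.

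**Figure D4:**
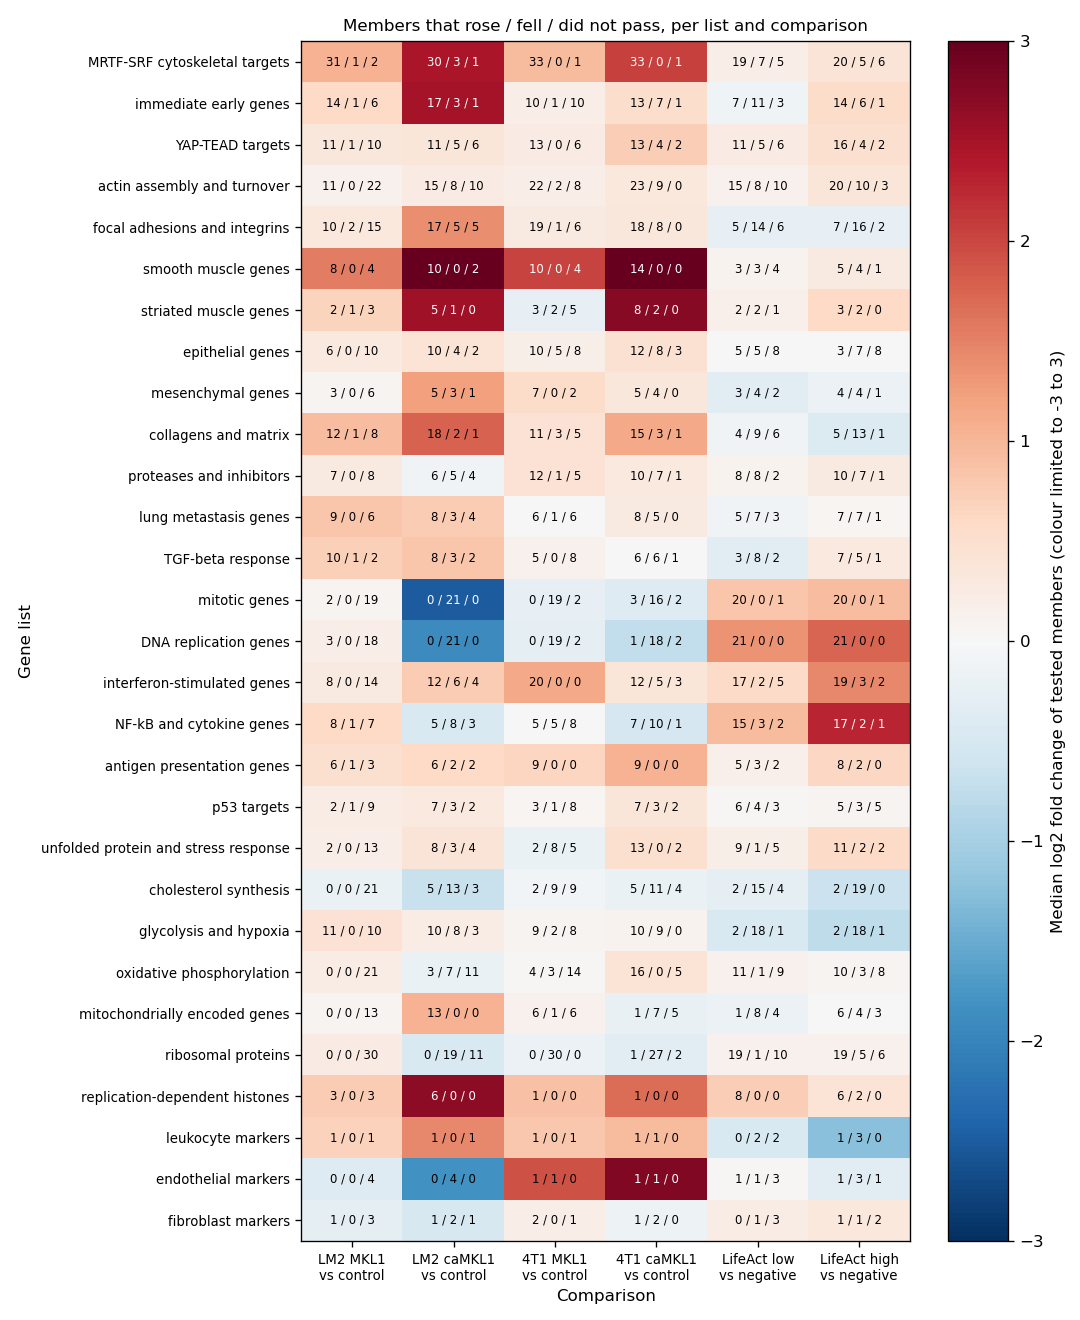
Median log2 fold change (colour, limited to −3 to 3) of gene lists (vertical) in 6 comparisons against control or LifeAct negative (horizontal), with the numbers of members that rose, fell or did not pass. Smooth muscle and MRTF-SRF lists rise with MKL1 and caMKL1, while list medians near 0 change sign with library totals, such as YAP-TEAD targets in LM2 caMKL1 (0.36 and −0.04).

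The MKL1 and caMKL1 responses overlap within each cell line. In LM2, 962 genes rose in both against 436.9 for independent calls, and 544 fell against 296.0, with 215 and 165 called in opposite directions. In 4T1 the shared genes numbered 2262 higher (1138 for independent calls) and 1831 lower (877.7), and in LifeAct low and high 5129 (2041) and 4575 (1818). These pairs share their control libraries, and the controls, 3 per experiment, cannot be divided into separate sets. Simulated counts with no change gave a mean of 0, 0.05 and 0.05 shared calls. Unchanged groups leave few genes to call, so these means are no baseline for the overlap of changed genes. Correlations of log2 ratios were 0.498, 0.472 and 0.527 in the simulated counts against 0.583, 0.634 and 0.857 observed. Spearman correlations were 0.461, 0.420 and 0.473 in the simulated counts against 0.292, 0.499 and 0.849 observed. Correlations of unchanged groups come from the shared control libraries alone. They are no baseline for groups with many changed genes, and the LM2 value below its simulated one cannot decide on an excess. The observed covariances were 0.701, 0.496 and 0.610 against 0.0304, 0.0156 and 0.0226 simulated.

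Across cell lines, 1732 of 10361 matched genes rose with caMKL1 in both lines (1317 for independent calls) and 2124 fell (1649), with a correlation of 0.349. The responses differed for 7341 genes by a test of the difference, 4248 more positive in 4T1 and 3093 more negative, or 5220 and 2343 with library totals. CNN1, TAGLN and CCN2 are among them: CNN1 rose 5.35-fold in LM2 and 4626-fold in 4T1, TAGLN 336-fold and 28.2-fold, and CCN2 33.5-fold and 3.96-fold. MRTFA and SRF did not pass this test (differences of −0.34 and −0.23 on the log2 scale, adjusted p = 0.0706 and adjusted p = 0.109). Human genes raised at least 2-fold by caMKL1 in LM2 were also raised in 4T1, where 890 of 1527 rose and 392 fell (camera adjusted p = 4.8e-07, adjusted p = 3.6e-06 with an estimated correlation). Those lowered showed 849 falls and 391 rises of 1516 (camera adjusted p = 1.5e-05, adjusted p = 0.0123 with an estimated correlation).

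The relation between the LifeAct and caMKL1 responses depended on the measure. Of 3023 tested genes raised at least 2-fold by caMKL1 in LM2, 1138 rose and 969 fell in LifeAct high cells (camera adjusted p = 0.580), and 674 rose and 826 fell in low cells (camera adjusted p = 0.333). With an estimated correlation these became adjusted p = 0.0374 upward and adjusted p = 0.0026 downward, opposite directions in the 2 groups. Of these raised genes 37.6% rose and 32.1% fell in high cells, against 35.7% and 35.7% of the other genes. In low cells the shares were 22.3% and 27.3%, against 26.5% and 23.0% of the other genes. Of the genes lowered by caMKL1, 963 rose and 1227 fell in high cells (camera adjusted p = 0.214, adjusted p = 0.397 with an estimated correlation), and 924 rose and 793 fell in low cells (camera adjusted p = 0.531, adjusted p = 0.638 with an estimated correlation). These were 34.6% and 44.1% in high cells, against 36.1% and 33.9% of the other genes. In low cells they were 33.2% and 28.5%, against 24.9% and 22.9%. Calls shared between LM2 caMKL1 and LifeAct high numbered 2295 higher (2205 for independent calls, Fisher exact p = 0.0015) and 2309 lower (2061, Fisher exact p = 7.9e-17). Against these stand 1673 genes raised by caMKL1 and lower in LifeAct high and 2579 with the reverse. No number for independent calls was computed for these opposite calls, so they cannot be read as an excess. The Fisher p-values take genes as independent units and measure no spread between libraries. The correlation was 0.114, or 0.00104 among genes of at least 5 CPM. TOP2A and RRM2 went opposite ways, at −2.73 and −2.64 with caMKL1 and 1.29 and 2.40 in LifeAct high on the log2 scale.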

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

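The tests of mitochondrial RNA, ACTB reads, Acta2 reads and library scaling were chosen after the results were seen, and the tests of ribosomal RNA removal, gene length and other splits before.

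The response to caMKL1 differed between the cell lines for 11 of the 13 genes followed throughout. On the log2 scale, 4T1 minus LM2, the differences were 9.75 for CNN1, 5.36 for MYL9, 2.90 for ACTA2, 2.15 for ACTG1, 1.89 for MRTFB, 1.44 for TPM1 and 0.61 for CCN1. The negative ones were −3.58 for TAGLN, −3.08 for CCN2, −0.79 for ACTB and −0.59 for VCL. All kept their sign and call with library totals and with limma voom. The lines differ in species, and the cause of these differences was not tested. Control levels also differed, with MYL9 at 55.2 to 61.2 CPM in LM2 but 0.0321 to 0.414 CPM (1 to 11 counts) in 4T1. With caMKL1, MYL9 reached 2214 to 2671 CPM in LM2 and 325 to 334 CPM in 4T1, so its larger ratio in 4T1 is no higher level. Cnn1 had 4 or 5 counts in each 4T1 control library.

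MT-RNR1 and MT-RNR2 rose together in LifeAct low libraries. In high libraries their means of 4.16 and 5.98 CPM were also above those of negative libraries (2.71 and 3.32), with adjusted p = 0.337 and adjusted p = 0.136. More mitochondrial RNA in these libraries is argued against by the 13 mitochondrial messenger RNAs, whose median log2 ratio was −0.18. The summed CPM of nuclear ribosomal RNA names in low over negative was 0.831 (55.4 ± 3.62 negative, 46.1 ± 2.09 low, 32.97 ± 1.97 high). Multi-mapped reads are left uncounted by default, and these RNAs come from repeated genes. This sum therefore cannot decide on weaker removal of ribosomal RNA in general. Weaker removal, in general or limited to the mitochondrial pair, stays open, and MT-RNR1 varied from 27.5 to 102.3 CPM between the low libraries. A change in mitochondrial transcription or ribosomes in the cells would look alike and was not tested.

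The muscle actins share most of their coding sequence with ACTB, which itself rose with caMKL1. Reads of ACTB counted at the muscle genes would keep a fixed ratio to the ACTB counts. Summed ACTA2, ACTG2 and ACTC1 counts were 32.4% to 46.3% of the ACTB counts in LM2 caMKL1 libraries. In 12 LM2 control and LifeAct libraries they were 0.0224% to 0.102%, so the lowest caMKL1 ratio was 318 times the highest of these. In 4T1, the ratio of Actc1 to Acta2 counts was 17.5 times as high in the lowest caMKL1 library as in the highest MKL1 library. This argues against reads of Acta2 alone. How the counts divide among the muscle actins stays open. A direct effect of MRTFA on each gene, or an effect through other factors, was not tested.

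The 42 mitotic and DNA replication genes were lower with caMKL1 in LM2 and nearly all higher in LifeAct low and high cells. Library scaling is argued against by their median log2 ratio of −2.31 with an SD of 0.615, against a largest scaling shift of 0.461, and all 42 were lower under each scaling. Gene length is argued against too, since the median was −2.51 after removing the trend with exon length. Slower division with caMKL1, or a difference in cell-cycle phase between the LifeAct groups, may explain these genes and was not tested.

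For each of the 9 comparisons, splits of the 6 libraries that called as many genes as the real grouping numbered 1 of 10, the real grouping itself, and 10 splits are too few for a share under 0.05. The real groupings called 2265 to 15554 genes and the other 81 splits at most 0 by edgeR, with 74 to 1347 genes at unadjusted p under 0.05. Each other split put libraries of both groups on both sides. A real difference then raises the spread within the sides, so few calls were likely there and their absence adds no support.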

How the results depend on the processing

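All alternatives except the joint leave-out of replicate 1 of MKL1 and caMKL1 and the leave-outs for correlations were fixed before the results were seen. Counts of changed genes were the same by the preset criteria in 126 of the alternative fits and weaker in 12. Same means a total within 1.5 times the main total, whatever the direction or identity of the genes. Under library totals LM2 MKL1 kept this label while its split went from 1369 higher and 896 lower to 918 and 1241. Requiring a change beyond 1.5-fold (glmTreat) left 381, 7170 and 7003 genes in LM2 (MKL1, caMKL1, and caMKL1 against MKL1), 514, 4667 and 3659 in 4T1, and 2050, 7373 and 1779 in LifeAct (low, high, and high against low). Leaving out libraries moved the LM2 MKL1 count from 1118 without control replicate 3 to 2452 without MKL1 replicate 3. Leaving out control replicate 1 or 2 also lowered it by more than 1.5 times, and no other leave-out moved a count that far. The other ranges were 11169 to 12122 and 11134 to 12049 in LM2, 4657 to 5227, 11113 to 11370 and 10233 to 10494 in 4T1, and 9632 to 10322, 14589 to 15007 and 9736 to 10312 in LifeAct. Without a filter on low counts LM2 MKL1 had 2092 higher and 808 lower genes, so the share of rises depends on the filter. That fit also computed scaling and spread anew, so the part due to genes near the detection limit was not separated. The cause of the dependence on control libraries was not tested.

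Replicate numbers were not treated as pairing in the main fits, a choice fixed before the data were examined. Not every same-numbered pair of libraries deviated together (correlation over 0.1). The pairs that did were 5 of 9 in LM2, 5 of 9 in 4T1 and 1 of 9 in LifeAct, and a library correlated best with its own number in 10, 10 and 5 of 18 tests. All 3 pairs of MKL1 with caMKL1 in LM2 did (0.535, 0.507 and 0.150), so a shared origin of these libraries is not excluded. All 3 pairs among the replicate 3 libraries, controls included, did so in LM2 (0.374, 0.176 and 0.150) and in 4T1 (0.371, 0.218 and 0.270). A shared origin of the replicate 3 libraries within each line is therefore not excluded either. Different-numbered pairs reached 0.491 in LM2 (MKL1 replicate 2 with caMKL1 replicate 3) and 0.191 in 4T1. With the replicate number as a block the counts were 3258, 12831 and 12711 in LM2, 6096, 11989 and 11125 in 4T1, and 10851, 15518 and 11020 in LifeAct.

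Overlaps and correlations moved with their threshold. With changes of at least 1 on the log2 scale the shared calls were 554 in LM2, 423 in 4T1, 1910 in LifeAct, 1119 for LM2 caMKL1 against LifeAct high and 653 between the lines, and at adjusted p under 0.01 those of LM2 numbered 717. In that order, correlations for genes of at least 5 CPM were 0.609, 0.740, 0.883, 0.00104 and 0.431, and Spearman correlations 0.292, 0.499, 0.849, 0.0663 and 0.251. Simulated groups with no change but shared controls gave Spearman correlations of 0.461, 0.420 and 0.473 in the 3 experiments. These hold for unchanged groups and are no baseline where many genes changed, so they cannot decide whether 0.292 in LM2 is an excess. Leaving out libraries gave 0.553 to 0.607, 0.593 to 0.654, 0.839 to 0.861, 0.0863 to 0.130 and 0.343 to 0.352. Part of the excess of shared calls over independent calls within an experiment may come from the shared controls. For LM2 caMKL1 against LifeAct high, the shared calls of at least 1 on the log2 scale were 509 higher against 348 for independent calls and 610 lower against 341 (Fisher exact p = 4.6e-22 and p = 3.1e-56), while the correlation at 5 CPM or more was 0.00104.

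Of the named genes, 16476 alternative values were the same, 68 stronger, 138 weaker and 1 reversed. The reversed value is Mrtfb in 4T1 caMKL1 with library totals (−0.083, adjusted p = 0.0514, within a range of adjusted p = 0.0117 to adjusted p = 0.220 over its alternatives). MRTFA between the LM2 constructs lost its call with library totals (adjusted p = 0.451, the highest of a range from adjusted p = 3.9e-05), and MRTFB in LM2 MKL1 without any one control library. Of the list tests 2388 were the same, 128 stronger, 152 weaker and 2 reversed, both with fry in 4T1 caMKL1 against MKL1, where proteases and inhibitors (adjusted p = 7.3e-07) and TGF-beta response genes (adjusted p = 8.7e-05) pointed upward, while the other alternatives gave adjusted p = 0.618 to 0.786 and adjusted p = 0.710 to 0.789. With the estimated correlation alone, 107 list tests were weaker and 160 the same, and same includes lists with no call in either setting. In LM2 caMKL1 against control no list passed with it (lowest camera adjusted p = 0.0653). Leave-outs of 1 library made up 1552 of the same results and kept the preset correlation of 0.01. The pooled totals therefore do not show that list calls hold without that preset. Depth was not varied.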

Other observations

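With caMKL1, 2184 of the matched genes were called in opposite directions in the 2 cell lines, against 3856 called in the same direction. No number for independent calls was computed for the opposite ones, so 2184 cannot be read as an excess. CDKN1A rose 31.3-fold in LM2 (adjusted p = 4.2e-12), while Cdkn1a decreased by 2.01 on the log2 scale in 4T1 (adjusted p = 1.0e-15). The p53-linked death receptor FAS rose in each line, 8.18-fold and 4.67-fold.

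The YAP-TEAD target ANKRD1 rose in all 6 comparisons with control or LifeAct negative, 2.41-fold and 11.3-fold with MKL1 and caMKL1 in LM2, 1.41-fold and 6.90-fold in 4T1, and 2.46-fold and 6.10-fold in LifeAct low and high cells. KRT19 rose with caMKL1 (23.6-fold in LM2, 6.71-fold in 4T1) and fell in LifeAct low and high cells (−0.69 and −1.60 on the log2 scale).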
